A study of Homo sapiens with 12 samples.

How the data were processed

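Poly(A) RNA of NOMO-1 cells was measured in 12 libraries, in 6 groups of 2: shNS and shALKBH5 at 0, 8 and 12 h in actinomycin D. The libraries were made with a stranded kit and sequenced on an Illumina instrument, per the labels' protocols. The labels' treatment protocol names lentivirus against FTO and the drugs CS1 and CS2, while titles and groups name ALKBH5 hairpins and actinomycin D, and the titles were followed. The submitters' processing notes name STAR, RSEM and GRCh38, and their versions and settings are not given in the sources used here. The deposited values are an expression signal per gene symbol, and the unit that entered the authors' scaling is not given in the sources used here. The median of the 46 ERCC spike-in transcripts lay between 29.9 and 33.1 in every library while the gene total fell with time, so the deposited signal is apparently scaled to the spike-ins, a step that no label states. A change over time is therefore read as a change per unit of spike-in, and it holds only as far as that scaling does.

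The shNS columns carry a replicate number that matches the labels. The knockdown columns carry the letters D and E, which recur at each time and were used as line names. Which letter is which of the 2 hairpins is not given in the sources used here, so the planned comparison of the hairpins was made as line D minus line E. Nothing says that the replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical. Each knockdown group holds 1 library of each hairpin, so its spread includes differences between hairpins. The deposited values hold no counts and no value of 0, so read depth is unknown and no counting interval was given.

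All 9529 genes were tested, since each had a mean of at least 1 over the libraries, the lowest being 1.30. Of their symbols 9144 were found in GENCODE release 29 and 385 were not, and coordinates are from that release. CDKN1A, which the rule for named genes lists, was not analysed here. Values were tested as log2(signal + 1) in R 4.3.3 with limma 3.58.1, with a mean-variance trend and empirical Bayes, and Benjamini-Hochberg adjusted p under 0.05 was called. A model of 6 group means gave the comparisons at 0 h, the changes by 8 and 12 h in each arm and the differences of these changes between arms. An additive model of time and knockdown gave the comparison across times, a model of hours, knockdown and their product gave the difference of slopes in log2 per hour, and a model of time and line gave line D minus line E. Percent left is the signal at a later time over that at 0 h in the same replicate or line.

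Of 30 gene lists fixed in advance, the 23 with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, under which no list was called in any comparison, and with fry. Markers of other cell types were too few to test: 0 of the erythroid, epithelial and kidney lists, 2 of the lymphoid list and 1 of the megakaryocyte list were among the tested genes. Genes were named by a rule: ALKBH5, FTO, METTL3, METTL14, YTHDF2, TACC3 and MYC in the knockdown comparisons, the 8 called genes with the largest rise and the 8 with the largest fall that had a mean of at least 5 and no overlap between the groups, and up to 4 members of each called list, of which the text gives a part. Of the genes the rule picked, 1 is not reported here. These comparisons, lists, rules and all alternatives not named below as added were set before the data were examined.

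The alternatives were a mean of at least 5, no filter (which removed no gene, so that setting is void), median-of-ratios scaling, scaling to the ribosomal protein genes, a pseudocount of 0.1, limma without trend, the line as a replicate block, each hairpin line alone, slopes from 2 times only, and leaving out each library in turn. A library left alone in its group is assumed to vary like the other groups. Added after the data were seen were a rescaling to the mean log2 of the ERCC transcripts, the block together with median-of-ratios scaling, a slope model with a time factor shared by both arms, without and with the block, the comparison across times without the 12 h or the 8 h libraries, and that comparison on the mean of each line or with a correlation estimated within the lines. The procedure was tested on simulated data with changed genes among 9529. For the comparison at 0 h it recovered 42.4% of genes changed by 1 log2 unit and 92.5% of those changed by 2, across times 95.5% and 98.5%, and for the difference of the 8 h change 22.7% and 82.1%. The simulated libraries were independent, with no correlation within a line and no shift common to the genes of a library. These shares therefore hold only for such libraries, which matters most for the comparison across times.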

Results

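NOMO-1, a human cell line established from an acute myeloid leukaemia with monocytic features, was used with a non-targeting hairpin (shNS) or 1 of 2 hairpins against ALKBH5, per the titles of the samples, while the labels' treatment protocol names lentivirus against FTO. ALKBH5 is a demethylase that removes N6-methyladenosine (m6A) from RNA. Poly(A) RNA was sequenced after 0, 8 and 12 h in actinomycin D, a drug that stops transcription. The fall of an mRNA is given per unit of spike-in and was not separated from a fall common to all RNA. Ribosomal RNA fell as well. By 12 h the shNS replicates kept 12.0% and 12.8% of their 18S signal and 11.9% and 12.9% of their 28S signal. Their median mRNA kept 11.9% and 12.9%, so percent left may not be a measure of mRNA decay alone. At 8 h the values lay apart, the shNS replicates keeping 34.9% and 20.6% of their 18S signal and 42.2% and 41.1% of their median mRNA. In the knockdown libraries they lay apart at 12 h as well. How far poly(A) libraries capture ribosomal RNA was not tested. The 12 libraries formed 6 groups of 2. Each shNS group held 2 replicates, and each knockdown group held 1 library of each hairpin, called here line D and line E after the letters in the headers of the deposited table. The table held 9529 genes and 46 ERCC spike-in transcripts in a normalised signal. The total signal of the genes lay between 826000 and 953211 at 0 h, between 390103 and 580217 at 8 h and between 143765 and 193639 at 12 h. The median ERCC signal lay between 29.9 and 33.1 in all 12 libraries. Read depth is unknown, so no counting interval was given. Log2 fold changes are on the log2(signal + 1) scale, which understates the change of low genes, and are given with their standard errors (SE).

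ALKBH5 itself (chromosome 17, 18183078 to 18209954, plus strand, GRCh38) was lower in every knockdown library than in both shNS libraries of the same time. At 0 h its signal was 84.3 and 78.6 in the shNS replicates, 25.4 in line D and 21.2 in line E, which is 31.2% and 26.0% of the shNS mean. At 8 h it was 35.9 and 32.1 in shNS, 1.52 in line D and 4.29 in line E, and at 12 h it was 8.22 and 8.30 in shNS, 0.636 in line D and 0.973 in line E. At 0 h the change was -1.77 (SE 0.29, adjusted p = 0.0202), and it missed the threshold in 7 of 20 alternatives. These were without either shNS library at 0 h (adjusted p = 0.268 and 0.176), without either at 8 h (0.0556 and 0.0552), without line D at 0 h (0.109), with a pseudocount of 0.1 (0.0753) and scaled to ribosomal protein genes (0.0520). Across the 3 times ALKBH5 fell by 2.46 on the log2 scale (SE 0.21, limma adjusted p = 1.01e-06, n = 6 against 6), and it was called in all 24 alternatives. The other m6A genes were closer to control. Across times FTO, the other m6A demethylase, stood at -0.06 ± 0.13 (SE). The methyltransferase genes METTL3 and METTL14 stood at 0.28 ± 0.15 (SE) and -0.35 ± 0.13 (SE), and the m6A reader YTHDF2 at 0.08 ± 0.15 (SE), none past the threshold. METTL14, with an adjusted p of 0.0636, passed in 5 of 24 alternatives (range 0.000244 to 0.376), among them without shNS replicate 2 at 0 h (0.0304) and without line D at 0 h (0.0184). METTL3 passed in 2 (0.00160 to 0.715) and YTHDF2 in 1 (0.0231 to 0.988).

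**Figure D1:**
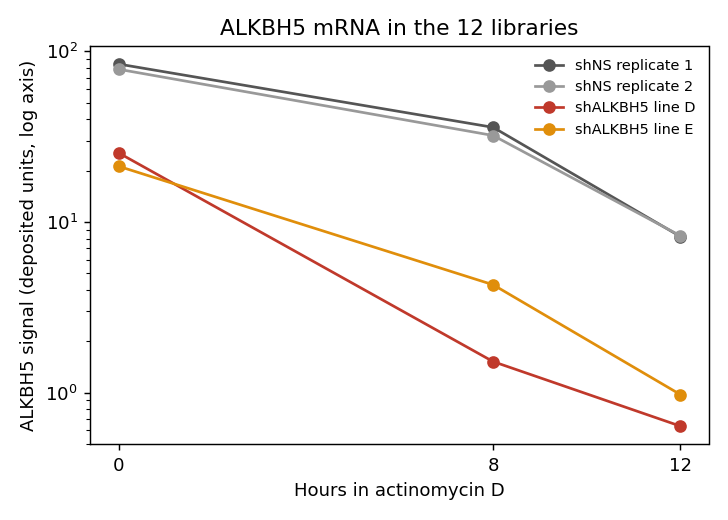
ALKBH5 signal in deposited units on a log axis against hours in actinomycin D, with 1 point per library and 1 line per shNS replicate or hairpin line. Both knockdown lines lie below both shNS replicates at each time, from 25.4 and 21.2 against 84.3 and 78.6 at 0 h to 0.636 and 0.973 against 8.22 and 8.30 at 12 h.

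Before actinomycin D, the genes with the largest rises in the knockdown lines included DEFB1, CAMP, S100A9 and SLPI, and GPR146 had the largest fall among the called genes named here. DEFB1, which encodes an antimicrobial defensin, stood at 10.5 ± 0.199 (SD, n = 2) in shNS and 145 ± 27.2 in the knockdown, a rise of 3.66 (SE 0.28, adjusted p = 0.000122). CAMP, the cathelicidin gene, rose by 2.23 (SE 0.26, adjusted p = 0.00430), and S100A9, a subunit of calprotectin, by 1.91 (SE 0.35, adjusted p = 0.0301). SLPI, an inhibitor of granule proteases, rose by 1.66 (SE 0.21, adjusted p = 0.00757). RNASE2 rose by 1.57, SLA by 1.61, LGALS12 by 1.59 and TP53INP2 by 1.95. Among the falls, GPR146, which encodes an orphan receptor, moved by -2.12 (SE 0.24, adjusted p = 0.00430), PLD6 by -1.45 and the oxysterol receptor gene GPR183 by -1.40. LINC01226 moved by -1.33, ZFP36L1, which encodes an mRNA decay factor, by -1.17, SH3BP5 by -1.09 and EAF1 by -1.04. MYC stood at 0.38 ± 0.21 (SE) and TACC3, which encodes a spindle protein, at 0.34 ± 0.22 (SE), with adjusted p of 0.312 and 0.381. With line D as the only knockdown line they stood at 0.58 and 0.56. The TACC3 signal was 148% of the shNS mean in line D and 109% in line E.

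Of the gene lists, myeloid differentiation had 4 of 23 tested members called higher at 0 h and 0 lower (6 and 0 adjusted over the list alone): ELANE, the neutrophil elastase gene, at 1.45 (SE 0.24, adjusted p = 0.0202), CTSG, the cathepsin G gene, at 1.41, CD68 at 1.14, and S100A9. Its camera adjusted p was 0.0154, and the adjusted p = 0.833 with an estimated correlation. The nucleolar MYC target list had 1 of 30 members called higher (12 adjusted over the list alone), the polyamine gene SRM at 0.82. The proteasome list had 0 of 36 called (17 higher adjusted over the list alone), with PSMD3 at 0.79 ± 0.19 (SE). Cholesterol synthesis had 0 of 23 (6 higher adjusted over the list alone), with DHCR7 at 0.77 ± 0.21 (SE). Glycolysis had 1 of 19 called lower (3 adjusted over the list alone): the glucose transporter gene SLC2A1 fell by 0.94. HK2 stood at -1.37 ± 0.31 (SE, adjusted p = 0.0504) and ENO2 at -1.92 ± 0.54 (SE, adjusted p = 0.0886). They missed the threshold in 13 and 15 of 20 alternatives. HK2 was -1.70 in line D and -1.04 in line E, and ENO2 -2.63 and -1.20. Of the immediate early list ZFP36L1 was called lower (2 higher and 4 lower adjusted over the list alone). None of the 82 ribosomal protein genes, 39 mitosis genes or 17 leukaemia self-renewal genes was called, and none adjusted over the list alone. For these 9 lists camera gave adjusted p between 5.22e-07 and 0.0368, and the adjusted p = 0.833 with an estimated correlation in each. Camera placed mitosis, immediate early and leukaemia self-renewal genes lower than other genes although their medians were 0.08, 0.15 and 0.02. With median-of-ratios scaling these medians turned to -0.17, -0.07 and -0.21.

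At 0 h, limma called 127 genes higher and 13 lower among 9529, while the median of all genes stood 0.23 higher in the knockdown. With median-of-ratios scaling, which takes that median shift to -0.01, 9 genes were called higher and 26 lower, 19 of the 35 being calls of the deposited scale in the same direction. Then S100A9, ELANE, CTSG, CD68, RNASE2, LGALS12, TP53INP2 and SRM no longer passed, because their estimates came down by 0.26 to 0.39, about the median shift or more, with little change in SE, and because fewer calls in all raise the adjusted p of each gene. S100A9 went from 1.91 (SE 0.35) to 1.54 (SE 0.40, adjusted p = 0.133), ELANE from 1.45 (SE 0.24) to 1.19 (SE 0.22, adjusted p = 0.0637) and RNASE2 from 1.57 (SE 0.22) to 1.30 (SE 0.22, adjusted p = 0.0521). Of the genes named here DEFB1 alone was called in all 20 alternatives. CAMP (adjusted p = 0.125) and GPR146 (0.118) were lost only without shNS replicate 1 at 0 h, and the others in 2 to 13. The count also moved with each library. It was 1 and 3 without the shNS 0 h replicates, 13 without either at 8 h and 18 without either at 12 h. It was 8 without line D at 0 h, 381 without it at 8 h, and 244 without it at 12 h, and 1018 without line E at 0 h, 388 without it at 8 h and 246 without it at 12 h.

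Across the 3 times, DEFB1, CAMP, S100A9 and SLPI were again higher in the knockdown lines, and ENO2 and the glucose transporter genes were lower. DEFB1 rose by 3.38 (SE 0.16, adjusted p = 1.99e-10), and CAMP by 1.90 (SE 0.15, adjusted p = 8.05e-07). S100A9 rose by 1.66 (SE 0.19, adjusted p = 2.70e-05) and SLPI by 1.37 (SE 0.14, adjusted p = 9.12e-06), with 6 libraries against 6 that come from 2 lines or replicates each. TP53INP2 rose by 1.51, CCND3, the cyclin D3 gene, by 1.49, LGALS12 by 1.44 and ITGAM, which encodes the myeloid integrin CD11b, by 1.33 (2.25 in line D and 0.42 in line E). Falls were seen for the neuronal enolase gene ENO2 at -2.16 (SE 0.27, adjusted p = 5.22e-05), PFKFB4, a regulator of glycolysis, at -2.07 (-3.39 in line D and -0.75 in line E), and the glucose transporter genes SLC2A3 at -2.04 (-3.38 in line D and -0.69 in line E) and SLC2A1 at -1.53. Others were the collagen hydroxylase gene P4HA1 at -1.77 and the mitophagy gene BNIP3 at -1.69. HSPA1A, a heat shock gene, stood at -2.25, a value that is uncertain because a near-identical copy, HSPA1B, shares its reads. MYC rose by 0.44 (SE 0.14, adjusted p = 0.0298), and missed the threshold in 9 of 24 alternatives. These were with line means (0.260), with a correlation within lines (0.115), without shNS replicate 1 at 0 h (0.0629) or 12 h (0.0918), shNS replicate 2 at 8 h (0.0706) or 12 h (0.0881), line D at 0 h (0.0506) or 12 h (0.0757), and without all 12 h libraries (0.379). TACC3 stood at -0.14 ± 0.15 (SE) with an adjusted p of 0.552.

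Grouped by list, 9 of 23 myeloid differentiation genes were called higher and 1 lower across times (9 and 2 adjusted over the list alone), with CD68 at 1.11, ELANE at 1.15 and CTSG at 1.11. Glycolysis had 1 of 19 higher and 11 lower (1 and 13 adjusted over the list alone), with HK2 at -1.62 and PDK1 at -1.44. Of the 36 proteasome genes 13 were higher and 0 lower (16 and 0), with PSMC4 at 0.72, PSMD6 at 0.66 and PSMD3 at 0.58. Of 30 nucleolar MYC targets 11 were higher and 1 lower (13 and 1), with RRP9 at 0.98 and RRP12 at 0.75. Cholesterol synthesis had 5 of 23 higher and 0 lower (7 and 0), with INSIG1 at 1.04 and SQLE at 0.66. Mitosis genes were lower in 14 of 39 and higher in 1 (18 and 1), with NUF2 at -0.86 and TOP2A at -0.65. Immediate early genes were lower in 7 of 19 and higher in 1 (11 and 2), with PPP1R15A at -1.35. Small nucleolar RNA host genes were lower in 8 of 18 and higher in 1 (10 and 2), with GAS5 at -0.76 and SNHG5 at -0.89. Ribosomal protein genes were lower in 24 of 82 and higher in 0 (40 and 1), with RPL7 at -0.79 and RPL3 at -0.67. The comparison across times averages levels before and after transcription was stopped, and at 0 h no mitosis or ribosomal protein gene was called. The median of all genes stood at 0.23 at 0 h, and its difference of the 8 h change was -0.48. These falls need not have been present before actinomycin D. The mRNA decay genes were lower in 6 of 42 and higher in 3 (6 and 3), with PAN2 at -0.91. Camera called these 10 lists at adjusted p between 4.55e-12 and 0.0399, and for each the adjusted p = 0.941 with an estimated correlation. Fry, which tests whether a list moves on balance in 1 direction, called myeloid differentiation and glycolysis, at adjusted p of 0.0178 and 0.0344. Of the 22 m6A machinery genes 4 were lower, ALKBH5, IGF2BP2 at -0.66, WTAP at -0.59 and PCIF1 at -0.58, and 0 higher (0 higher and 5 lower adjusted over the list alone). PCIF1 missed the threshold in 10 of 24 alternatives. These were with line means (0.145), with a correlation within lines (0.0875), scaled to ribosomal protein genes (-0.28, adjusted p = 0.2003), without the 12 h libraries (0.198) or the 8 h libraries (0.114), without either shNS library at 8 h (0.0833 and 0.0658) or 12 h (0.0668 and 0.0633), and without line D at 12 h (0.0783). With line means IGF2BP2, WTAP, PSMC4, PSMD6, PSMD3, SQLE and TOP2A missed it as well (0.0695 to 0.143), and WTAP also with a correlation within lines (0.0621). Without the 12 h libraries these 7 and NUF2, GAS5, RPL7 and RRP12 missed it (0.0516 to 0.175), and without the 8 h libraries WTAP, NUF2, GAS5, RPL7, RPL3 and TOP2A (0.0576 to 0.138).

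Limma called 1137 genes higher and 871 lower across times among 9529, with a median of all genes of 0.02. This fit counts the 3 libraries of a line as independent, which overstates the replication, since the deviations of line D correlated between times at 0.657 to 0.900. With the mean of each line over the times, 2 against 2, limma called 259 genes higher and 231 lower, all 490 being calls of the fit above in the same direction. With a correlation estimated within lines (0.251) it called 519 higher and 399 lower, and both choices were made after the data were seen. Scaling to the ribosomal protein genes moved that median to 0.30 and the calls to 4573 higher and 338 lower. Under it the median of the m6A machinery and mRNA decay lists turned from -0.10 and -0.15 to 0.16 and 0.13. Median-of-ratios scaling gave 1852 higher and 1821 lower. Without the 12 h libraries, a choice made after the data were seen, 246 genes were higher and 184 lower. The balance of directions moved with single libraries. It was 1194 higher and 499 lower without shNS replicate 1 at 8 h, and 778 higher and 987 lower without shNS replicate 2 at 0 h. The count of 2008 was 1221 and 1228 without shNS replicate 1 or 2 at 12 h, and 1292 without shNS replicate 2 at 8 h.

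**Figure D2:**
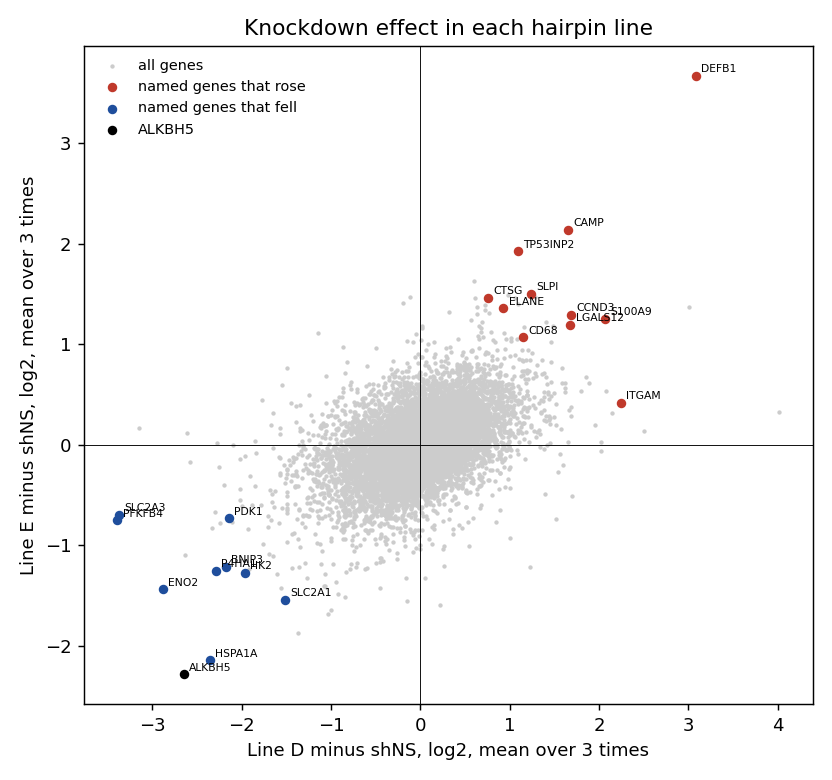
Log2 difference from the shNS mean in line D (horizontal axis) and line E (vertical axis), each averaged over the 3 times, with 1 grey point per gene and named genes coloured. DEFB1, CAMP and S100A9 lie above 0 and ALKBH5, ENO2 and SLC2A1 below 0 in both lines, and the correlation across genes is 0.474.

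The libraries of lines D and E shared part of their difference from shNS and also differed from each other. Compared with line E, line D held more MMP1, the interstitial collagenase gene, with a difference of 3.70 ± 0.18 (SE), and more ARPC1A at 2.44. It held more of the scavenger receptor gene CD36 at 2.36, more of the lysosomal glycoprotein gene GPNMB at 2.25 and more DCT at 2.21. It held less ATP5B, a subunit of the mitochondrial ATP synthase, at -3.32 ± 0.19 (SE), and less of the splicing gene SNRPC at -2.73. Lower too were SLC2A3 at -2.68, PFKFB4 at -2.64, HSD17B4 at -2.40 and the antigen presentation gene CD74 at -2.26. At 0 h the ATP5B signal was 192 in line D, 943 in line E and 718 and 689 in shNS. That of MMP1 was 138, 11.9 and 8.99 ± 1.16 (SD, n = 2). ALKBH5 stood at -0.36 ± 0.19 (SE), adjusted p = 0.126, between the lines, and missed the threshold in 16 of 18 alternatives (-0.80 to 0.14). It passed with a pseudocount of 0.1 (-0.57, limma adjusted p = 0.0230) and without line D at 0 h (-0.80, adjusted p = 0.00024). In list tests added after the data were seen, camera called 7 lists between the lines. Glycolysis genes were lower in line D in 8 of 19 and higher in 0 (8 and 0 adjusted over the list alone, camera adjusted p = 3.87e-06), and cholesterol synthesis genes in 10 of 23 and 0 (10 and 0, 0.00910). Relative to other genes, camera placed proteasome (0.0109), DNA replication (0.0109), zinc finger (0.0109), mitosis (0.0219) and heat shock genes (0.0219) higher in line D. The adjusted p = 0.982 for each with an estimated correlation, and fry called none.

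Limma called 1354 genes higher and 1423 lower in line D than in line E. Without line D at 0 h the calls were 907 higher and 1987 lower, so the balance of directions depended on single libraries. Each side is 1 line at 3 times, so these p-values compare those libraries and have no replicate of a hairpin behind them, and the count of 2777 was 1469 without line E at 8 h. In this joint fit of all libraries against the shared shNS libraries, 2118 genes were called higher and 1925 lower in line D, and 1113 higher and 1009 lower in line E. In separate fits that left the other line out, the counts were 3465 in line D and 4016 in line E, so the order of the lines depends on the fit. The lists of the joint fit had 595 higher and 523 lower genes in common, and 109 genes were called in opposite directions. Independent lists of these sizes would share 247 and 204. Both lists rest on the same shNS libraries, so they are not independent and part of the excess is built in. Across genes, which are not independent replicates, the effects of the lines correlated at 0.474, where simulated libraries with no effect against the same controls gave 0.335. Their covariance was 0.0840 against 0.00333 with no effect, and with the shNS replicates split between the lines the correlation was 0.452 and 0.463, each line then having 1 control library per time. The simulation drew independent libraries with the spread of the shNS replicates. It therefore holds neither the spread between lines D and E nor the correlation within a line. The residual spread of this fit was nearly the same for all genes, which makes its p-values very small.

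After transcription was stopped in shNS cells, MYC, DDIT4, XBP1 and CITED2 had the largest falls among the named mRNAs, and the lists of ribosomal protein and glycolysis mRNAs kept more of their signal than the median gene. MYC had 2.48% ± 0.310 (SD, n = 2) of its 0 h signal at 8 h and 1.07% ± 0.0174 at 12 h, a change of -5.96 (SE 0.21, adjusted p = 4.37e-09) by 12 h. DDIT4, a stress-induced inhibitor of mTOR, changed by -5.86, XBP1, a factor of the unfolded protein response, by -5.49, and CITED2 by -5.41. BYSL changed by -5.31, GFI1 by -5.20, the mRNA decay factor gene ZFP36L2 by -5.08 and PSMG2 by -5.06. At 8 h the falls were led by MYC at -5.06, DDIT4 at -4.78, CITED2 at -4.34, XBP1 at -4.01, KCNE3 at -3.92 and IRF2BP2 at -3.88. The genes that rose were short non-coding RNAs. How far poly(A) libraries capture such RNAs was not tested, so a rise of their signal need not be a rise of the RNA. RPPH1, the RNA of ribonuclease P, rose by 0.83 (SE 0.25, adjusted p = 0.00667) by 12 h (adjusted p = 0.0992 without shNS replicate 2 at 0 h). SCARNA17 rose by 0.82 and SNORD3A by 0.72 by 8 h.

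The median gene kept 41.8% of its signal at 8 h and 12.5% at 12 h in shNS. Ribosomal protein mRNAs kept 88.1% and 29.6% (median of 82), and glycolysis mRNAs 79.6% and 34.9% (19). Nuclear oxidative phosphorylation mRNAs kept 75.1% and 23.1% (78) and myeloid differentiation mRNAs 67.3% and 23.6% (23). In that last list CEBPA and CEBPB, myeloid transcription factor genes, changed by -4.61 and -4.63 by 12 h. Mitosis mRNAs kept 6.59% at 12 h (39), with PLK1 at -4.74 and CKAP5 at -4.58. Zinc finger mRNAs kept 25.4% and 7.99% (168), and m6A machinery mRNAs 8.81% at 12 h (22), with YTHDF2 at -4.37 and FTO at -3.57. Nucleolar MYC targets kept 30.6% and 8.12% (30), DNA replication mRNAs 35.2% and 7.67% (37) and mRNA decay mRNAs 35.0% and 9.02% (42). By 12 h all tested members of these lists were called lower except 3 of myeloid differentiation, 2 of glycolysis and 1 of oxidative phosphorylation, and the same held adjusted over the list alone. Relative to all other genes, camera placed myeloid differentiation (7.15e-06), glycolysis (0.000162), ribosomal proteins (0.000330), oxidative phosphorylation (0.00161) and small nucleolar RNA host genes (0.0310) upward. It placed mitosis (0.000155), nucleolar MYC targets (0.00149), DNA replication (0.00634), m6A machinery (0.00870), mRNA decay (0.0218) and zinc finger genes (0.0218) downward, each number being an adjusted p. With an estimated correlation the adjusted p was 0.180 for myeloid differentiation and 0.795 for the other 10.

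Limma called 3 genes higher and 7830 lower at 8 h, with a median of -1.15, and 1 higher and 9484 lower at 12 h, with a median of -2.56, among 9529. On the median-of-ratios scale, where these medians are 0.04 and 0.01 and a value is a change relative to the median gene, 1804 genes were higher and 2245 lower at 8 h and 2341 higher and 2573 lower at 12 h. There ribosomal protein mRNAs stood at 1.26 (median, 77 higher and 2 lower) and glycolysis mRNAs at 1.49 (11 higher and 2 lower).

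**Figure D3:**
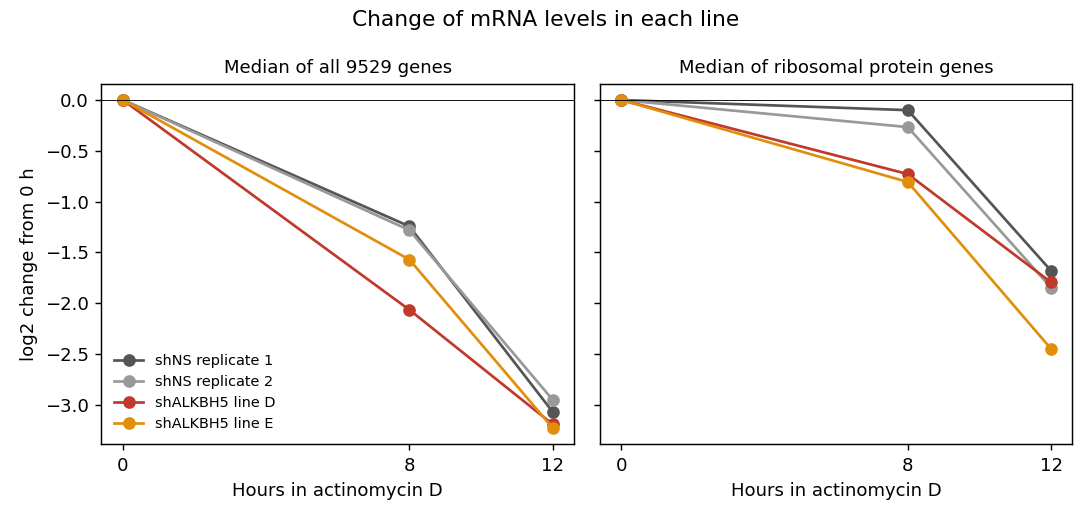
Median log2 change of signal from 0 h against hours in actinomycin D in each shNS replicate and hairpin line, for all genes (left) and for ribosomal protein genes (right). At 8 h the all-gene medians of lines D and E, -2.07 and -1.57, lie below those of the shNS replicates, -1.24 and -1.28.

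In the knockdown lines the largest falls by 12 h were those of CITED2 at -5.85, MYC at -5.62 (SE 0.21, adjusted p = 4.13e-09), DDIT4 at -5.56, and GFI1 at -5.32. Others were the cell cycle inhibitor gene CDKN1B at -5.13, USP1 at -5.13, the chemokine receptor gene CXCR4 at -5.12 and XBP1 at -5.08. At 8 h they were led by CITED2 at -5.25, MYC at -5.21, DDIT4 at -5.11, SNORD36A at -4.43 and BRIX1 at -4.41. In these poly(A) libraries the signal of RN7SK, a small nuclear RNA that restrains transcription elongation, rose by 1.80 (SE 0.32, adjusted p = 0.000111) by 12 h and by 1.20 by 8 h. SNORD3A rose by 1.23 and 1.05, and SCARNA17 by 0.60 by 8 h. The median gene kept 23.9% of its signal in line D and 33.6% in line E at 8 h, and 10.9% over both lines at 12 h. Ribosomal protein mRNAs kept 59.0% and 23.5%, glycolysis mRNAs 55.2% and 18.7% and mitosis mRNAs 16.4% and 4.47%.

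Limma called 3 genes higher and 9151 lower at 8 h, with a median of -1.66, and 2 higher and 9487 lower at 12 h, with a median of -2.80 (n = 2 against 2). With median-of-ratios scaling the calls were 2026 higher and 2258 lower at 8 h and 2110 higher and 2302 lower at 12 h, relative to the median gene.

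Whether loss of ALKBH5 altered mRNA stability was asked by comparing the change over time between the arms. TACC3 kept 28.6% ± 2.28 (SD, n = 2) of its signal at 8 h and 12.3% ± 0.230 at 12 h in shNS, and 17.7% ± 2.59 and 7.03% ± 0.104 in the knockdown, differences of -0.68 ± 0.31 (SE) and -0.75 ± 0.31 (SE) on the log2 scale. MYC kept 1.07% ± 0.0174 in shNS and 1.62% ± 0.00262 in the knockdown at 12 h, a difference of 0.34 ± 0.30 (SE). ALKBH5 kept 41.7% ± 1.17 and 13.1% ± 10.1 at 8 h, a difference of -1.49 ± 0.40 (SE). Its mRNA is the target of the hairpins, so this difference cannot show an effect of losing ALKBH5 on stability. Its signal at 8 h was also low, 1.52 in line D and 4.29 in line E. YTHDF2 and METTL14 differed by -0.79 ± 0.31 (SE) and -0.73 ± 0.26 (SE) at 8 h. None of these passed the threshold with both lines in the fit and no block. The adjusted p was 0.299 at 8 h for ALKBH5, TACC3, YTHDF2 and METTL14 and 0.985 at 12 h for TACC3 and MYC. With line D as the only knockdown line, the differences at 8 h were -2.15 for ALKBH5, -1.09 for YTHDF2, -0.88 for METTL14, -0.83 for TACC3 and -0.63 for FTO. At 12 h they were -0.86 for ALKBH5, -0.76 for TACC3 and 0.74 for METTL3. That fit has 1 knockdown library per time, so it holds no spread between knockdown libraries. TACC3 kept 15.9% in line D and 19.5% in line E at 8 h, and 7.10% and 6.95% at 12 h. In the test of slopes TACC3 differed by -0.07 ± 0.04 (SE) log2 per hour in the knockdown, KLF4 by -0.10 ± 0.03 and the heat shock gene HSPA1A by -0.14 ± 0.05, each with an adjusted p of 0.999. That test fits a straight line in hours to each arm, so any bend of the fall over time widens its SE. Its adjusted p of 0.999 is therefore no evidence that the slopes were equal.

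By list, the slope differences of mitosis genes had a median of -0.05 log2 per hour (camera adjusted p = 2.16e-07), with KIF23 at -0.10 and CENPA at -0.10. Those of heat shock genes had a median of -0.06 (3.06e-05) with DNAJB1 at -0.11. Those of small nucleolar RNA host genes had -0.05 (0.0171) and those of published ALKBH5 targets -0.07 (0.0105), each lower relative to other genes. Leukaemia self-renewal genes had a median of -0.00 (0.02 with median-of-ratios scaling and 0.03 scaled to ribosomal protein genes) and lay higher relative to other genes (0.0171). The adjusted p was 0.938 for host genes and 0.792 for the other 4 with an estimated correlation, and fry called none. No member of these lists passed over all genes in this fit, and adjusted over the list alone 1 of the 5 tested ALKBH5 targets, KLF4, did. That list holds TACC3, which was reported from work on such cells, and is no independent evidence. With a time factor shared by both arms and the lines as a block, chosen after the data were seen, the slopes of HSPA1A (3.95e-06), SNHG1 (0.00112), DNAJB1 (0.00149), CENPA (0.00340), KLF4 (0.00416), KIF23 (0.0101), NUF2 (0.0279) and BMI1 (0.0326) were among the 135 that passed (8 higher, 127 lower), each of these lower in the knockdown. With the shared time factor and no block limma called 0 slopes, where 441 lay at an unadjusted p under 0.05.

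Limma called 0 of 9529 genes for the difference of the 8 h change, where 1560 lay at an unadjusted p under 0.05 (5 higher, 1555 lower), 0 for that of the 12 h change (337, of which 16 higher and 321 lower) and 0 for the slope (71, of which 9 higher and 62 lower). Median-of-ratios scaling raised the 337 to 793 and the 71 to 347, and scaling to ribosomal protein genes took them to 485 and 107. The 1560 became 252 with median-of-ratios scaling and 113 scaled to ribosomal protein genes. Without single libraries it became 238 (shNS replicate 1 at 8 h), 285 (shNS replicate 2 at 0 h), 885 and 887 (either at 12 h), 550 and 787 (line D at 0 and 8 h), and 2720 and 3788 (line E at 0 and 8 h). The 337 ranged from 88 (shNS replicate 1 at 12 h) to 1031 (line E at 0 h), and the 71 from 27 (shNS replicate 2 at 0 h) to 363 (line E at 0 h). A replicate block pairs the shNS libraries by their number, though their deviations correlated between times at only 0.271, 0.0651 and 0.138. Those of lines D and E correlated at 0.777, 0.657 and 0.900, and the fit without a block counts that lasting difference between the lines as spread. Its 0 calls are therefore no evidence that the changes were equal. With the lines as such a block the counts were 2493 at 8 h (10 higher, 2483 lower), 222 at 12 h (13 higher, 209 lower) and 2 for the slope. Then ALKBH5 (2.56e-06), YTHDF2 (0.0220) and METTL14 (0.0301) passed at 8 h, and with median-of-ratios scaling added they did not. The difference of ALKBH5, the target of the hairpins, went from -1.49 (SE 0.26) to -1.11 (SE 0.25, adjusted p = 0.267). What ended its call was not tested. Those of YTHDF2 and METTL14 shrank from -0.79 (SE 0.26) to -0.28 (SE 0.14, adjusted p = 0.468) and from -0.73 (SE 0.26) to -0.28 (SE 0.12, adjusted p = 0.419). With the block alone TACC3 passed at 8 h (adjusted p = 0.0320) and not at 12 h (0.0684). It missed the threshold in 20 of 22 alternatives at 8 h and in 20 of 22 at 12 h. With the block and median-of-ratios scaling, chosen after the data were seen, the counts were 2, 335 and 0, and TACC3 passed at 12 h (0.0448) and not at 8 h (0.683). Without line E at 0 h the counts were 7 at 8 h, 4 at 12 h and 3 for the slope, and without line E at 8 h 1 gene was called at 8 h.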

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

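The tests of relabelled single libraries were set in advance, and the division by whole lines and the tests on the fall by 8 h were chosen only after the result was seen.

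The libraries of lines D and E differed in level in 2777 genes in a direct test, which has 1 line on each side and so no replicate of a hairpin. No other of the 10 splits of the 6 knockdown libraries into 3 and 3 called a gene (highest 0), but 10 splits are too few for a share under 0.05, the real split being 1 of them. Called in opposite directions against shNS in the lines were 109 genes. MMP1 stood 3.70 higher on the log2 scale in line D than in line E, and ATP5B stood at -3.32. Of the 46 ERCC transcripts, which no comparison tested and which entered only the ERCC rescaling, 6 fell by over 0.5 log2 by 12 h in both shNS replicates and both knockdown lines, with a median change of -1.45, while 30 stayed within 0.5 and 0 rose by more.

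The 2008 genes called between shALKBH5 and shNS across times were more than in any other of 100 relabellings of the libraries within the times, the highest other count being 180 and the real one alone reaching its own count (1 of 100). This argues against a chance division only if single libraries are independent. Libraries of 1 line are not independent, however, since the deviations of line D correlated between times at 0.777, 0.657 and 0.900. With whole lines kept together, the 4 lines have 3 divisions into 2 and 2, of which the real one alone called genes (2008, highest other 0), and 3 divisions are too few for a share under 0.05. Each other division has a shNS replicate and a knockdown line on both sides. The difference between the arms then widens its spread, so few calls are built in whatever the cause.

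By 8 h the median mRNA fell further in the knockdown lines (-2.07 in D, -1.57 in E) than in the shNS replicates (-1.24 and -1.28). Whether line D alone accounts for it stays open because line E has 1 library at 8 h, whose median change lay -0.29 from the lower shNS replicate. With 1 knockdown line in the fit, the median difference of the 8 h change was -0.65 for line D and -0.29 for line E. Of the 2493 genes called with the lines as a block, 0.0802% stayed called once each library was also scaled to its median gene, their median difference going from -0.73 to -0.23 and their median SE from 0.25 to 0.16, which says little because that scaling removes any median shift. After that scaling the differences of lines D and E, each against a different shNS replicate, correlated across genes at 0.371, and at 0.291 with the replicates exchanged. What the shNS replicates share enters both differences, and nothing says that they are separate cultures. Whether a factor common to all mRNAs, and nothing else, accounts for the larger fall thus stays open. Whether the shift of the median is a faster general decay in the knockdown or comes from the spike-in scaling stays open: rescaling to the mean log2 of the ERCC transcripts, which was lower in the 8 h knockdown libraries (5.59 and 5.57) than in shNS (5.70 and 5.68), moved the median difference from -0.48 to -0.36, while the 18S RNA signal left at 8 h ran the other way (45.9% and 45.5% in lines D and E, 34.9% and 20.6% in shNS).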

How the results depend on the processing

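The ERCC rescaling, the block with median-of-ratios scaling, the shared time factor, the line means, the correlation within lines and the runs without 1 time were chosen after the data were seen, all others before. Where a count moved and no reason is given, the cause was not tested. Fits with 1 hairpin line hold 1 knockdown library per time and no spread between the lines, so their counts cannot be set against the others. ALKBH5 across times was called in all alternatives (-2.90 to -2.07). At 0 h (140 calls) the count was 82 with a mean of at least 5, 35 with median-of-ratios scaling, 74 scaled to ribosomal protein genes, 18 with a pseudocount of 0.1, 5006 in line D alone, 2078 in line E alone, and 1 to 1018 without single libraries. Across times (2008) it was 3673, 4911 with the scalings, 3465 in D, 4016 in E, 430 without the 12 h libraries, 490 with line means, 918 with a correlation within lines and 1221 to 2319 without single libraries. Median-of-ratios scaling gave 4049 (shNS, 8 h), 4914 (shNS, 12 h; 2318 in the opposite direction), and 4284 and 4412 (knockdown, 8 and 12 h), because it sets the median gene to 0 change. It gave 5045 for D minus E (1469 to 3899 without single libraries), whose median it moved only from 0.02 to 0.03. By 12 h in shNS it turned FOXM1 to 0.32, SPI1 to 0.18, SLC2A1 to 0.11, CCAR1 to 0.44, TAF1D to 0.31 and RPL23 to 0.60. The differences of the 12 h change, 8 h change and slope (0 each) became 222, 2493 and 2 with the replicate block, 335, 2 and 0 with block and median-of-ratios scaling, 1293, 6285 and 6 in D, 224, 102 and 0 in E, and 0 to 4, 0 to 7 and 0 to 3 without single libraries; the shared time factor gave 0 slopes, and 135 with the block. Called lists went from 9 to 0 at 0 h, 10 to 0 across times, 11 to 0 in shNS and 5 to 0 for slopes with an estimated correlation, and to 3, 2, 23 and 0 with fry (20 across times in either direction, 23 in shNS, 0 for slopes). Deviations of shNS libraries with the same number correlated at 0.271, 0.0651 and 0.138, and whether they share more than a number was not tested. Those of lines D and E correlated at 0.777, 0.657 and 0.900. The block moved no count of the changes within an arm by over 1.5 times (8784, 9524, 9455 and 9524). No paired analysis was possible because the letters D and E match no shNS replicate number, for the comparisons of shALKBH5 with shNS at 0 h and across times, so across times the line entered as the unit (490 and 918 above), and line D minus line E compares the lines themselves. Of single named genes, 130 values at 0 h and 85 across times lost their call and 95 and 16 gained one. What depth limits could not be given, since it is unknown.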

Other observations

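The tests on hypoxia-responsive genes, on granule and lysosome genes and on the steepness of the fall were chosen only after the results were seen, and the relabelling of slopes was set in advance.

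Genes that respond to low oxygen were lower in the knockdown lines across times. BHLHE40, a circadian and hypoxia-induced repressor, stood at -1.62, NDRG1 at -1.44, MXI1, a MYC antagonist, at -1.29, the histone demethylase gene KDM3A at -1.23, VEGFA, the angiogenic growth factor gene, at -1.23 and EGLN1, an oxygen-sensing hydroxylase gene, at -0.74, each called by limma. Of 33 tested genes of a hypoxia-responsive list, none of them in the lists fixed earlier, 23 were lower, 0 higher and 10 not called. The list was written after ENO2, PFKFB4, SLC2A3, P4HA1 and BNIP3 had been seen to be lower. It was 1 of 2 lists written at that stage, and the other held granule and lysosome genes. Of its 18 tested members 5 were higher, 2 lower and 11 not called across times, and its median lay at percentile 96.6 in line D (0.25) and 98.6 in line E (0.16). At 0 h it lay at percentile 88.3 and 72.7, so it did not stand apart there.

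The lower glycolysis genes may therefore be part of a reduced expression of hypoxia-responsive genes, as a hypothesis. The median of the list lay at percentile 0 of 10000 matched random lists in line D (-0.91, random 0.00) and at percentile 0 in line E (-0.63, random 0.01), and at 0 h it was -0.61 and -0.42. Matched random lists ignore the correlation of genes that move together, and with that correlation estimated (0.392) camera gave p = 0.0311 (fry 0.000297), against 0.485 for the granule and lysosome list (unadjusted, 2 lists). The list was written after related genes had been seen to be lower, so the hypothesis needs other data. A difference in culture density or medium between the lines was not tested and stays open.

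From 8 to 12 h ribosomal protein mRNAs fell more steeply than before in all 4 lines. If each mRNA decayed at a constant rate, the last 4 h would bring 4/8 of the first 8 h, yet ribosomal protein mRNAs fell further than that by at least 0.70 (-0.70 in the line with the smallest excess). A factor common to all mRNAs, and nothing else, was also argued against, since their excess of -1.23 (mean of the lines) and that of the median mRNA, -0.73 (-1.12 and -0.96 in the shNS replicates, -0.02 in line D, -0.82 in line E), differed by -0.50 (SD 0.12), a bound of 2 SD that replaced one of 0.5 after this value had been seen. A mix of a common factor with other causes stays open.

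The slope test called 0 genes with the real labels, so all 100 of 100 relabellings reached that count by construction, which says nothing about chance. The highest other count was 470, in the split that exchanges the arms at 0 h alone, a structure of the libraries in which both arms stay apart at 8 and 12 h. The first principal component held 92.5% of the variance and the second 3.20%. The 18S RNA signal left was 34.9% and 20.6% in the shNS replicates and 45.9% and 45.5% in lines D and E at 8 h. At 12 h it was 12.0% and 12.8% in the shNS replicates, 22.8% in line D and 16.4% in line E. That of 28S RNA at 12 h was 11.9% and 12.9% in the shNS replicates, 27.6% in line D and 17.8% in line E. The median mRNA kept 11.9%, 12.9%, 10.9% and 10.7% in the same order.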
